A study of Cannabis sativa with 6 samples.

How the data were processed

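Leaf RNA of *Cannabis sativa* cv. Pink Pepper was sequenced in 3 control and 3 heat libraries. Per the labels' protocols, RNA was extracted with the RNeasy Micro kit and libraries were made with a TruSeq standard mRNA kit, which selects polyadenylated RNA. Per the submitters' processing notes, the tools were Trimmomatic 0.39 (a read trimmer), HISAT2 2.2.1 (an aligner), HTSeq 2.0.5 (a read counter) and DESeq2. The roles and settings of these tools, the genome build, the annotation and the use of strand were not given in the sources used here.

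Each library had 2 deposited files. The first held the authors' raw counts per gene, with 5 closing rows in the layout of HTSeq that name no gene and were left out of library sizes and tests. These rows held reads outside annotated exons, reads ambiguous between genes, reads that did not align, reads aligned to several places and reads of low quality; together they made up 11.2% of the listed reads in control and 15.9% in heat. The second file held a normalized signal per gene, which the authors had deposited as the same counts multiplied by one factor per library, as DESeq2 size factors give. Dividing by that factor returned whole reads for 100% of the values at a tolerance of 0.01, and these reads equalled the counts for all 34253 genes. Counts were therefore used throughout.

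Gene names and RNA classes came from a RefSeq gene table of the assembly ASM2916894v1 (cultivar Pink Pepper), which matched all 34253 rows, 33721 by symbol, 53 by locus tag and 479 as numbered copies of a tRNA symbol. Of the rows, 33673 carry a locus number as their only name. The table gave no product names, and its assembly is not named in the deposited sources, so it was used only for names, RNA classes, the order of neighbouring genes and which genes overlap or lie inside another, and none of its coordinates are given. Before the data were examined, 24 gene lists had been fixed by patterns in product names; without product names they were not tested. The rule for named genes, fixed at the same time, then gave the 2 largest rising and 2 largest falling genes by log2 fold change among those with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the groups, plus the 3 genes of highest mean CPM. RNA classes and functional groups of mitochondrial genes were taken in place of the lists after the data were examined, and the mitochondrial genes named are examples from those groups. Genes of the plastid genome were not analysed here.

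Differential expression was tested in R 4.3.3 with edgeR 4.0.16 on all 6 libraries (filterByExpr, TMM factors, robust dispersion, glmQLFit and glmQLFTest, two-sided), without a covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter left 17727 genes, and 10955 of the 34253 genes had a count in no library. CPM are counts per 1000000 of the tested library size times its TMM factor. The SE of a log2 fold change was its size divided by the square root of the F statistic. The common biological coefficient of variation was 4.67%. Gene sets were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, over 14 sets of at least 3 tested genes. Shares per library were compared with an exact permutation test, which cannot go below p = 0.1 with 3 libraries against 3. Against a group at 0 counts a fold was computed as a bound from 3 counts over the group. Intervals for ratios of summed counts are exact at 95% and, like the floors, cover counting error only.

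The edgeR, DESeq2 and limma-voom fits were tested on simulated data of the same 17727 genes and library sizes, with 200 genes changed. Far more genes were called in the real data, so the simulation does not test the scaling where most genes change. The other alternatives were not simulated. For the comparison of heat with control, edgeR recovered 51 of 67 genes changed 1.5-fold, 56 of 66 changed 2-fold and 63 of 67 changed 4-fold, with 11 false calls among 181. The alternatives were RLE, upper-quartile and total-count scaling, DESeq2 1.42.0, limma-voom, limma-trend on log2(value + 1) of the normalized signal, a looser and a stricter filter, a fold threshold, a replicate block and the removal of each library in turn. Added after the data were examined were the recovered reads, the removal of the mitochondrial genes and the removal of the 10 most abundant genes of either group.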

Results

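The transcriptome of leaves from young *Cannabis sativa* plants of the cultivar Pink Pepper was measured by mRNA sequencing in 2 groups of 3 libraries. The control plants were kept at 23 ± 1 °C, and the heat plants at 45 ± 2 °C, for 7 days at the same relative humidity. The comparison of the groups addresses how leaf gene expression differs after a week at high temperature. The labels do not say whether the 3 libraries of a group came from separate plants, so the p-values measure the spread between these libraries, which may be technical. The control libraries held 30766680, 33043083 and 36584253 gene counts, and the heat libraries 30012772, 28853936 and 28492832. Of 34253 annotated genes, 19633 ± 74.5 had a count in a control library and 20192 ± 69.9 in a heat library (SD, n = 3). The first principal component of log2 CPM held 96.9% of the variance and separated the groups, and the second held 1.01%. Within a group the libraries correlated across genes at r of at least 0.998, while their counts differed by more than sampling noise, with a chi-square per degree of freedom of 3.33 to 4.40 for the 6 pairs, which repeat preparations of the same RNA can give too.

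After 7 days at 45 °C nearly the whole leaf transcriptome differed from the control. Of 17727 genes tested, 7857 rose and 8218 fell at an adjusted p under 0.05, together 90.7% of them. With a log2 fold change of at least 1 in addition, 5284 rose and 6039 fell. At least 16-fold changes, with genes at 0 in one group set to the bound that 3 counts over the group allow, were found for 1047 rising and 1691 falling genes. The values of the groups did not overlap for 91.0% of the tested genes, where chance gives 10% for 3 libraries against 3. The median log2 fold change over all tested genes was -0.05. The scaling places the typical gene near no change, so rises and falls are relative to the library. A change in the total mRNA of the leaf would not be seen. The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. A test against a change of 2-fold rather than against no change (glmTreat) called 10419 genes, of which 4864 rose.

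**Figure D1:**
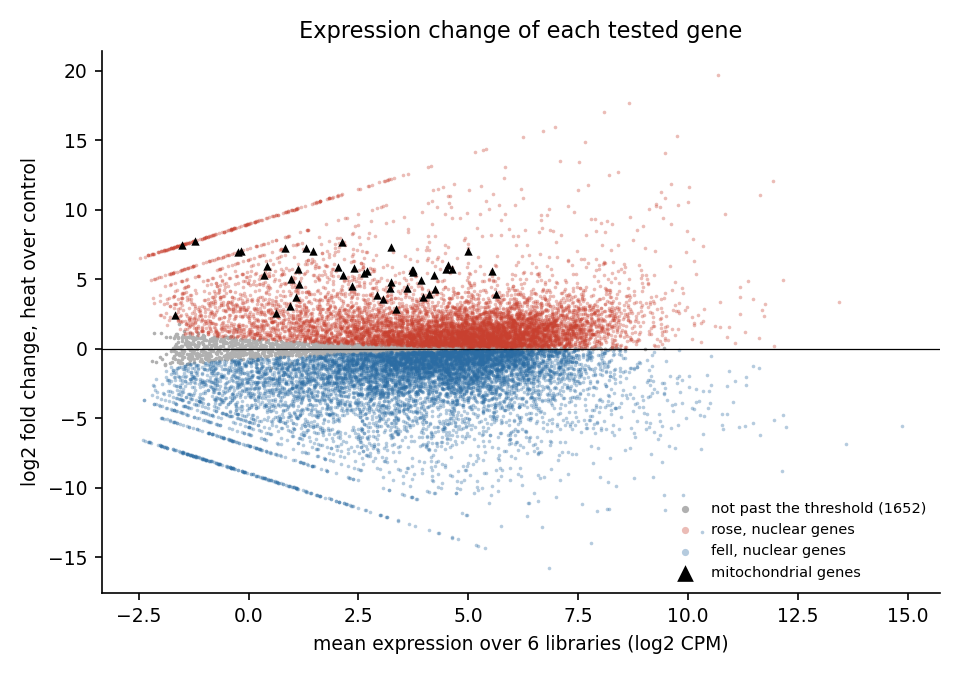
Each point is a tested gene, with its mean expression over the 6 libraries on the x axis (log2 CPM) and its log2 fold change, heat over control, on the y axis. Red points are the nuclear genes that rose, blue points those that fell, grey points the genes not past the threshold, and black triangles the genes of the mitochondrial genome; rising and falling genes were spread over all expression levels, and the straight bands at the edges are genes with 0 or few counts in one group.

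The most abundant transcripts of the leaf differed between the groups. LOC115715128, the gene with the highest mean level over all libraries, fell from 58386 ± 897 CPM in control to 1226 ± 22.8 CPM in heat (SD, n = 3), a log2 fold change of -5.57 ± 0.04 (SE; edgeR adjusted p = 9.84e-42). It alone took 5.97% ± 0.0646 of the gene counts of a control library. LOC115714527 fell from 24693 ± 978 to 212 ± 8.62 CPM, a log2 fold change of -6.86 ± 0.04 (edgeR adjusted p = 1.46e-41). LOC133034289 rose in the other direction, from 2023 ± 122 to 20149 ± 1081 CPM, a log2 fold change of 3.32 ± 0.05 (edgeR adjusted p = 3.03e-23). These are the 3 genes of highest mean CPM. Of the 100 most abundant genes over all libraries, 50 rose and 50 fell. The lists of the 100 most abundant genes of each group had 13 genes in common. The 10 most abundant genes of a library held 14.2% ± 0.0757 of the gene counts in control and 7.40% ± 0.119 in heat (exact permutation test, two-sided, p = 0.1, the smallest that 3 libraries against 3 can give; adjusted p = 0.1 over the 20 shares and totals compared this way).

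Some genes passed from no detectable transcript to an abundant one, or the reverse. LOC115712088 had 0 counts in each control library and 93433, 94310 and 92762 counts in the heat libraries, 3286 ± 103 CPM, at least 112261-fold higher in heat against a floor of 3 counts over the control group. LOC115712164 had 0 counts in control and 812 ± 30.2 CPM in heat, at least 27764-fold higher. LOC115723301 stood at 228 ± 1.43 CPM in control and at 0 counts in each heat library, at least 6496-fold lower. LOC115720789 stood at 83.8 ± 1.86 CPM in control and at 0 counts in heat, at least 2387-fold lower. These are the 2 largest rises and the 2 largest falls, with edgeR adjusted p of 1.24e-41, 9.79e-40, 1.58e-36 and 5.77e-32. With a lower threshold, the count of genes near 0 in one group was larger on the falling side. The heat libraries were shallower, so a threshold in counts favours genes near 0 in heat. Over a group, 3 counts allow 0.0351 CPM in heat and 0.0292 CPM in control. How much of the difference this gives was not tested. At most 3 counts in every control library and at least 1 CPM in every heat library were seen for 284 genes, of which 236 were protein-coding and 28 long non-coding RNA (lncRNA) genes. The reverse was seen for 412 genes, of which 402 were protein-coding and 9 lncRNA genes. Genes at 0 counts throughout one group are a smaller set. With at least 1 CPM in each library of the other group, they numbered 144 at 0 in heat and 120 at 0 in control. Of these, 27 at 0 in heat and 26 at 0 in control had a mean of at least 10 CPM in the other group. At a mean of at least 100 CPM they numbered 1 and 6.

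Counts on the mitochondrial genome rose together. All 35 of its protein-coding genes were tested and all 35 rose, by a median log2 fold change of 5.29 (39.2-fold), from 2.59 for rps19 to 7.65 for ccmC. Those with few control counts passed the count filter through the heat libraries alone, so a fall could not have been called for them. The filter left out none of the 35. Control counts of ccmC were 2, 2 and 0, and its log2 fold change was 7.04 without control replicate 3. Their summed share went from 31.3 ± 7.25 to 806 ± 4.98 per 1000000 gene counts (SD, n = 3), 25.8 times higher (exact permutation test, two-sided, p = 0.1, the smallest possible; adjusted p = 0.1 over 20 measures). In the same libraries the share of all listed reads that fell outside annotated exons went from 1.79% ± 0.0634 to 6.05% ± 0.108. Poorer poly(A) selection or RNA quality in the heat libraries, or mitochondrial DNA in them, cannot be told apart here from an effect of heat on mitochondrial transcripts. As a set against the other tested genes the 35 genes were called by camera (adjusted p = 1.60e-07), a call lost at adjusted p = 0.192 with an estimated correlation. Mitochondrial genes and RNA classes were grouped after the data were examined.

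The groups named here hold only genes of the mitochondrial genome; the nuclear genes of the same complexes were not analysed here as groups. All 8 mitochondrial genes of complex I (NADH dehydrogenase, which feeds electrons into the respiratory chain) rose, by a median log2 fold change of 5.55. The gene nad2 went from 0.809 ± 0.211 to 44.4 ± 1.12 CPM, a log2 fold change of 5.76 ± 0.12 (SE), and nad6 rose least of the 8, by 3.69 ± 0.32. Both mitochondrial genes of complex II (succinate dehydrogenase) rose, sdh3 by 5.85 ± 0.34 and sdh4 by 3.06 ± 0.30. Control counts of sdh3 were 4, 0 and 10, and its log2 fold change was 5.26 without control replicate 2 and 6.94 without control replicate 3. All 4 mitochondrial genes of complexes III and IV rose. Of these cox1, the catalytic subunit of cytochrome c oxidase, went from 1.94 ± 0.438 to 90.7 ± 0.701 CPM (log2 fold change 5.54 ± 0.08), and cob, cytochrome b, from 2.08 ± 0.894 to 32.6 ± 1.75 CPM (3.96 ± 0.16). All 5 mitochondrial ATP synthase genes rose, among them atp1, the mitochondrial gene with the most counts in each control library, from 6.12 ± 0.936 to 93.4 ± 4.85 CPM (3.93 ± 0.07). The smallest rise of the 5 was that of atp8, 2.87 ± 0.14. Camera called the mitochondrial genes of complex I (adjusted p = 0.00675; 0.192 with an estimated correlation), complexes III and IV (adjusted p = 0.0327; 0.325 with an estimated correlation) and ATP synthase (adjusted p = 0.0327; 0.350 with an estimated correlation). Reads of cox3 and sdh4, which overlap in the annotation, can be counted as ambiguous between the pair.

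The 4 mitochondrial genes of cytochrome c maturation, which attach haem to cytochrome c, rose by the largest median of the mitochondrial protein-coding groups, 7.11 on the log2 scale. The gene ccmFn went from 0.117 ± 0.0517 to 18.8 ± 1.58 CPM (log2 fold change 7.28 ± 0.22), and ccmFc rose by 5.57 ± 0.25. Control counts were few in this group, and all 4 genes passed the count filter through the heat libraries alone. A fall could therefore not have been called for them, and their camera call is in part given by the filter. The gene ccmB had 1 count over the control group and 143 over the heat group, a ratio of 172 with an exact 95% counting interval of 30.3 to 6828. Its fitted log2 fold change went from 6.93 to 8.68 without control replicate 2, which held that count. All 10 ribosomal protein genes of the mitochondrial genome rose, by a median of 4.71. Among them rps3 went from 2.21 ± 0.777 to 28.9 ± 2.48 CPM (3.71 ± 0.14) and rpl2 from 0.666 ± 0.102 to 18.1 ± 1.05 CPM (4.76 ± 0.17). The maturase gene matR, whose product acts in intron splicing, rose by 7.01 ± 0.12, from 0.479 ± 0.196 to 63.1 ± 2.35 CPM, and the transporter gene mttB by 4.97 ± 0.37. All 3 mitochondrial rRNA genes rose, rrn5 by 5.67 ± 0.16, rrnS by 5.71 ± 0.39 and rrnL by more than either. These 3 genes also passed the count filter through the heat libraries alone. Of 15 mitochondrial tRNA genes 6 had enough counts to be tested, and all 6 rose (camera adjusted p = 0.0327; 0.192 with an estimated correlation), while camera did not call the rRNA genes (adjusted p = 0.0771). The 6 tRNA genes had 0 to 8 counts in each control library and passed the count filter through the heat libraries alone. Their rise and their camera call were therefore largely given by the filter. Camera called cytochrome c maturation (adjusted p = 0.0415) and the ribosomal proteins (adjusted p = 0.00356), both at adjusted p = 0.192 with an estimated correlation. The first of these was also lost with camera on ranks (adjusted p = 0.0586) and under a stricter count filter (adjusted p = 0.0557), over a range of 0.0205 to 0.192 for its camera alternatives.

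**Figure D2:**
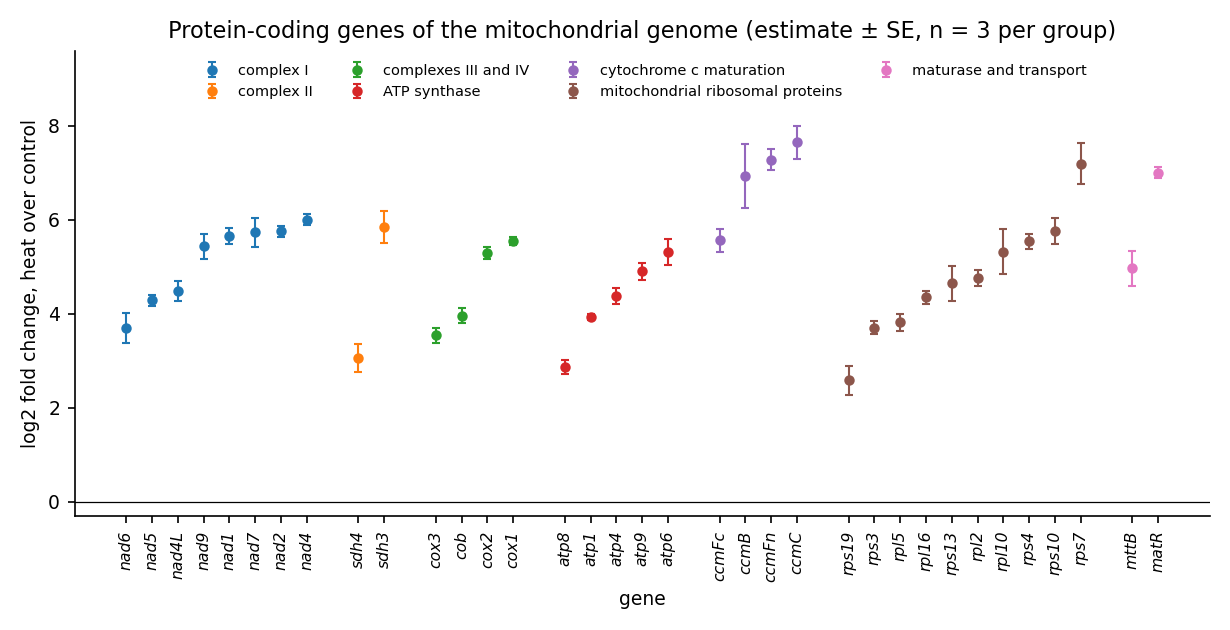
The log2 fold change, heat over control, of each of the 35 protein-coding genes of the mitochondrial genome, by functional group, as the edgeR estimate (points) with its SE (bars), from 3 libraries per group. All 35 genes lie above 0, from rps19 at 2.59 to ccmC at 7.65.

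Small nucleolar RNAs (snoRNA), which guide the modification of ribosomal RNA, rose as a class. Of 116 nuclear snoRNA genes tested, 99 rose and 0 fell, by a median log2 fold change of 2.98. Of the 116, 8 had 0 counts in every control library, and 0 had 0 counts in every heat library. These 8, and any others too low in control, passed the count filter through the heat libraries alone and could only rise. How many others did so was not counted, so the lack of falls and the set test are in part given by the filter. At an unadjusted p under 0.05 in edgeR, 0 fell, and 0 fell by DESeq2 or limma-voom. The share of all 1894 snoRNA genes, taken without the filter, went from 54.1 ± 2.65 to 332 ± 7.93 per 1000000 gene counts, 6.14 times higher (SD, n = 3). The exact permutation test, two-sided, gave p = 0.1, the smallest possible (adjusted p = 0.1). Beside this rise, and that of the tRNA genes below, reads outside annotated exons rose from 1.79% to 6.05% and the assigned share fell from 88.8% to 84.1%. Camera called the class at adjusted p = 2.43e-08, and at adjusted p = 0.0281 with an estimated correlation. With the requirement of 1 CPM in 3 libraries, which tests fewer of these short genes, 60 rose. Of 14 nuclear tRNA genes tested 12 rose and 1 fell, TRNAN-GUU_3, from 4.19 ± 0.297 CPM to 0.128 CPM in heat. The 9 tested tRNA genes with 0 control counts were all below 3 CPM in heat, and near-identical tRNA copies share reads, so single tRNA genes are uncertain. These 9 genes passed the count filter through the heat libraries alone and could only rise, and the set test of tRNA genes includes them. Camera called the nuclear tRNA genes at adjusted p = 0.00581, lost at adjusted p = 0.192 with an estimated correlation and at 0.440 under the filter of 1 CPM in 3 libraries, over a range of 0.00337 to 0.440 for its camera alternatives. Of 7 tested genes of spliceosomal and other small nuclear RNA (snRNA) 4 rose and 2 fell (camera adjusted p = 0.392), and of 7 tested genes of other RNA kinds 3 rose and 3 fell (camera adjusted p = 0.835).

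Among lncRNA genes more rose than fell. Of 578 tested, 308 rose and 186 fell, with a median log2 fold change of 0.74, and their share went from 6453 ± 247 to 16623 ± 194 per 1000000 gene counts, 2.58 times higher (SD, n = 3; exact permutation test, two-sided, p = 0.1, the smallest possible; adjusted p = 0.1). In the same libraries reads outside annotated exons went from 1.79% to 6.05%, and the share assigned to genes from 88.8% to 84.1%. Camera called the class upward at adjusted p = 0.0370, a call lost at adjusted p = 0.192 with an estimated correlation, at 0.0537 on ranks and at 0.180 without the count filter, over a range of 0.0189 to 0.192 for its camera alternatives. Nuclear protein-coding genes went both ways, with 7387 of 16961 rising and 8026 falling (median log2 fold change -0.10). As a class they stood lower than the other genes (camera adjusted p = 0.000898, and 0.0327 with an estimated correlation). The other genes are those of the RNA classes and the mitochondrial genome described above. The call therefore mirrors the rise of those genes and adds no separate result on protein-coding genes. The sources do not give whether the counting used strand, so lncRNA genes that overlap or face another gene are uncertain.

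The reads that were not assigned to a gene differed between the groups as well. Reads outside annotated exons were 3.37 times as frequent in heat. Reads that did not align made up 2.43% ± 0.148 in control and 3.09% ± 0.0929 in heat, and reads aligned to several places 4.22% ± 0.0442 and 5.07% ± 0.0735. Reads ambiguous between genes were less frequent in heat, 1.75% ± 0.0187 against 2.73% ± 0.00877. The share assigned to genes was 88.8% ± 0.178 in control and 84.1% ± 0.104 in heat. For each of these shares the groups did not overlap (SD, n = 3; exact permutation test, two-sided, p = 0.1, the smallest possible; adjusted p = 0.1 over 20 measures).

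**Figure D3:**
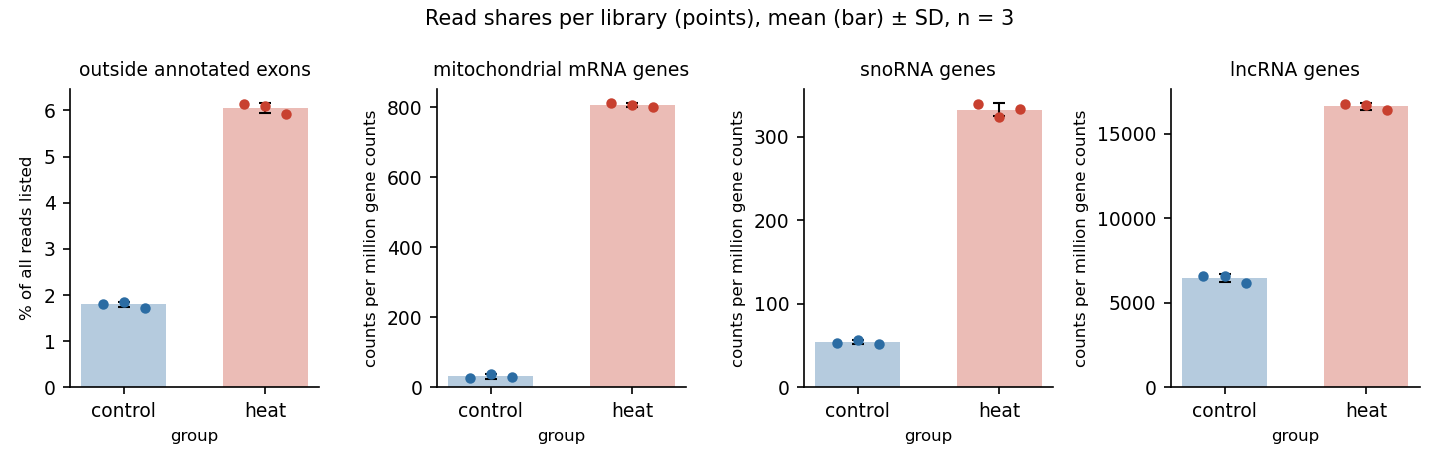
Share of reads per library (points), with the group mean (bars) and SD (error bars, n = 3), for control in blue and heat in red, with the axes starting at 0. The panels show reads outside annotated exons as a percentage of all listed reads, and mitochondrial protein-coding, snoRNA and lncRNA genes as counts per 1000000 gene counts; each heat library lies above each control library in all 4.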

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

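Of the tests in this part, only that of nested against other snoRNA genes was chosen before its result was seen. Of the reads outside the gene counts, which the comparison of genes does not use, 3 kinds stood above the control level in each heat library, while reads ambiguous between genes stood below it (1.75% against 2.73%). Reads outside annotated exons made up 6.05% of the listed reads in heat against 1.79% in control, reads that did not align 3.09% against 2.43%, and reads aligned to several places 5.07% against 4.22%.

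The rise of reads outside exons came with the rise of mitochondrial, snoRNA and tRNA transcripts, most of which lack the long poly(A) tail that the library kit selects. Nuclear DNA carried over into the heat libraries cannot account for the whole of it, since it would put reads on silent genes too, yet the 9303 protein-coding genes with 0 counts in every control library had a median of 0 counts over the 3 heat libraries, and 78.7% of them had none; of the 8365 with 0 counts in every heat library 87.5% had none in control, so a small amount carried over stays open. Of the snoRNA genes that do not lie wholly inside a protein-coding gene, 81.01% rose (64 of 79). Reads from inside unspliced protein-coding transcripts would not reach those that lie clear of such genes. Partial overlaps were not set apart, so this source is not excluded for all 79. Of the 37 nested ones 35 rose, a larger share than of the others, and this difference in share was not tested. Their median log2 fold change differed from that of the others by -0.24 (permutation test, two-sided, p = 0.573), which leaves that source open for them. Mitochondrial DNA stays open, since the 3 of 15 mitochondrial tRNA genes with 0 counts in heat may have lost their reads as aligned to several places. Poorer poly(A) selection or RNA quality in the heat libraries cannot be told apart from an effect of heat on these RNAs, on the lncRNA share that rose beside them or on polyadenylation, because the lowest heat library had 20.3 times the mitochondrial share of the highest control library and the libraries differ in the same way as the treatment.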

How the results depend on the processing

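The removal of the mitochondrial genes or of the most abundant genes, the recovered reads and the class and neighbour results were added after the data were examined. The count of changed genes was 16075 and lay between 15053 and 17625 under other scalings, tests and filters, the recovered reads giving 16075 again; it fell to 11323 with a log2 fold change of at least 1 and to 10419 in the test against a 2-fold change, where 4864 genes rose, since these ask for a larger change. Removing each library in turn gave 16045 to 16148 genes. The same-numbered libraries of the groups did not deviate together (correlations -0.015, 0.008 and -0.005), so no pairing by number was seen, which does not exclude one. The fit with a replicate block gave 15871 genes. No gene called both as reported and under an alternative changed sign, and the share of calls that rose stayed between 46.7% and 50.1%. Every scaling used was relative to the library, so this share would not show a change in total mRNA. The 7 named nuclear genes and the 35 mitochondrial protein-coding genes kept their direction and call in all 137 and 665 values under the alternatives. Rising snoRNA genes numbered 99, and 60 under the stricter filter of 1 CPM in 3 libraries, which tests fewer of them. They numbered more than 99 in each fit without 1 library, where the filter let more genes through (18009 to 18038 tested against 17727). Set tests were less stable: with an estimated correlation every called set other than snoRNA and nuclear protein-coding genes lost its call, and over the camera alternatives the adjusted p of the mitochondrial protein-coding set ran from 4.46e-09 to 0.192. The call of nuclear protein-coding genes mirrors those of the other classes, against which it was set. The mitochondrial tRNA set was also lost on ranks (camera adjusted p = 0.0586) and under the stricter filter (0.0995). The mitochondrial rRNA genes gained a camera call without control replicate 1 (adjusted p = 0.0461) or 2 (0.0491), against 0.0771; the cause was not tested. Values from fry, which tests a set against no change, bear on no camera call against other genes. The camera alternatives for the lists fixed by product name were not run. Of the short RNA classes, 116 of 1894 snoRNA and 14 of 527 nuclear tRNA genes had enough counts to be tested; the cause was not tested.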

Other observations

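The test on other splits was chosen after its result was seen, the present test on depth after the genes it concerns were seen and in place of an earlier one, and the neighbour tests before, but how the neighbour results count for an explanation was revised after they were seen. Genes that lie next to each other changed alike. Over 17234 pairs of adjacent tested nuclear genes, the Spearman correlation of the log2 fold changes was 0.143. Permuted positions gave a 95% range of -0.0136 to 0.0163 (permutation test, one-sided, p = 1e-05, the smallest that 100000 permutations can give). Genes are not independent replicates. Of adjacent genes that both changed, 55.1% went the same way, against 50.1% for permuted positions.

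The longest run of adjacent tested genes that all fell by a log2 fold change of at least 1 had 21 members, and the longest that all rose had 15. The upper end of the 95% range over 200 permutations was 11 for falling and 10 for rising runs. Runs of at least 6 genes numbered 52 falling and 35 rising, against a permuted mean of 17.1 and 8.16. In the falling run the summed level went from 255 ± 2.31 to 4.05 ± 1.46 CPM (SD, n = 3), 8 genes had 0 counts in every heat library and 13 had some. Its most abundant members, LOC115721041 at 54.1 CPM and LOC115720594 at 49.3 CPM in control, had 0 counts in heat; they and the run were picked after their values were seen. In the rising run of 15 protein-coding genes the summed level went from 17.6 ± 0.731 to 213 ± 2.91 CPM. Where genes of almost no counts were tested too, the longest falling run was 13 and the longest rising run 10; permutations were not run on that larger set of genes.

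A shared response of neighbouring genes to heat is one candidate explanation for this likeness, but the correlation of 0.143 is the likeness itself and does not test it. Tandem copies, or reads shared by directly adjacent genes, may give it too: the correlation was 0.0753 for genes 2 positions apart and 0.0075 for genes 5 apart, within the permuted range (p = 0.211). Both stay open, since no sequence was used here to tell copies from other neighbours.

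Genes at 0 counts in one whole group and at 1 CPM or more in each library of the other numbered 144 at 0 in heat and 120 at 0 in control. Shallow sequencing does not account for them: genes at 0 in one library and at 1 CPM or more in another numbered at most 1 for any pair of libraries within a group, against at least 218 for any pair across groups (0.459% of that), the deepest library, control replicate 3, among those at 0. Among the 241 of these genes placed on a chromosome (23 were left out), genes at 0 in the same group were neighbours in 8 pairs, against a permuted mean of 1.91 (permutation test, one-sided, p = 0.00067), which segments missing from the plants of one group would give, but shared regulation of neighbours could give it too. Near-identical copies that take each other's reads in plants of different genotype would put genes at 0 in opposite groups side by side. Of such pairs 0 were seen, but only 1.65 would be given by permuted positions (95% range 0 to 4). The bound set for this test before its result was therefore too loose to exclude such copies. The labels give 1 cultivar and no genotype per plant, and an effect of heat on these genes stays open as well.

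Among the 10 splits of the 6 libraries into 3 and 3, the real one gave 16075 changed genes in edgeR and the highest of the other splits 0, with at most 5 genes at an unadjusted p under 0.05 and 0 by limma-voom. Each other split placed heat and control libraries together in both of its parts. The difference between the groups then widened the spread within them, so counts near 0 were given in advance. The contrast with the real split therefore does not bear on the calls, and 1 split of 10 is too few for a share under 0.05.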
